A study of Mus musculus with 3 samples.

How the data were processed

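Single-nucleus RNA sequencing was done on punches of 500 µm diameter from sections of 200 µm through the lateral septum of 8 male mice, pooled before library preparation, with version 3 of a droplet kit and sequencing on a NextSeq or NovaSeq 4000, per the labels' protocols. The 3 libraries carry the same batch year, 2018, and form 1 group. Per the labels' protocols, tissue next to the lateral septum, such as cortex or striatum, can be present. The authors used Seurat 4 and the mouse build mm10, per the submitters' processing notes. The aligner, the filters on nuclei, the treatment of doublets and free RNA, the clustering settings and the test behind the p-values are not given in the sources used here.

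The data are 3 tables of cluster markers made by the authors. The authors give an average log2 fold change per gene and cluster, per the file headers, and its pseudocount is not given in the sources used here. Detection inside and outside a cluster is a fraction of nuclei with 3 decimals, per the file headers, and is written here as a percentage. The deposited p-values and adjusted p-values come from the authors' own test on nuclei, which are not independent animals, and are not used here to rank genes. The adjusted value was the raw value times a constant of 20574 in the broad table, 20044 in the GABA table and 18109 in the Sst table. Each cluster had 50 rows, each with a log2 fold change of at least 1 and higher detection inside than outside. The largest adjusted p was 2e-09, 6e-08 and 6.51e-07 in the broad, GABA and Sst tables, so the threshold of 0.05 removed 0 rows. The tables hold 1250, 1100 and 400 rows and 834, 705 and 353 different genes, in that order. The number of nuclei and the depth per nucleus or library are unknown, so no counting interval or detection floor was computed.

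Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Before the data were examined, a rule fixed the genes to be named: the 2 genes per broad cluster and GABA subcluster, and the 5 per Sst subcluster, of largest log2 fold change with adjusted p under 0.05 and detection of at least 25% inside. Added to these were Pdyn and Sst wherever listed, the markers of 19 cell types and, from each of 17 gene groups, the 4 members of highest log2 fold change per table. Members of a group beyond these, among them Tacr1, Oprk1, Oprm1, Htr1a, Htr1b, Htr2c, Lhx2, Nkx2-1, Penk, Tac1, Cort and Cartpt, and Prlr in an Sst subcluster, were chosen after their values were seen. A cluster was named by a cell type, as "like", when at least 3 of its markers were listed and its leading genes did not go against the name. GABA subcluster 20 and Sst subcluster 1 reached that count for lateral septum GABAergic neurons but were left unnamed. No clustering was done here, and the authors' cluster numbers were kept.

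For each gene listed in 2 or more clusters of a table, overall detection computed from each cluster must be equal, which gives linear equations in the shares of nuclei. They were solved by least squares from 286 genes in the broad table, 258 in the GABA table and 42 in the Sst table, and the genes were resampled 1000 times for the errors. The residual was about 0.02 percentage points in each table, the size of the rounding. The part of a gene's positive nuclei that lies in a cluster follows from the share and both detection values. On tables simulated with known shares the largest error was 0.073 points for the broad table, 0.051 for the GABA table and 0.063 for the Sst table. A list drawn from genes already listed for a single cluster of each real table reached the 100.0 percentile there, an outcome fixed by its making.

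Counts of list members per cluster were set against 10000 random lists of equal size drawn from the genes of the same table, matched in 5 bins of detection, and are given as the percentage of random lists with fewer members. These percentiles describe the tables and are not p-values over animals. Each list with at least 3 listed genes was tried for every cluster, without correction for the number of pairs. Some pairs over the 99th percentile can therefore arise by chance. The lists share some genes, so their counts are not independent. Clusters of different tables were matched by the number of shared genes and compared by detection inside. For a best-matching set, the sizes of its members were compared with those of 10000 random sets. Gene positions, spans and exon lengths came from GENCODE M21 on GRCm38, the same assembly as mm10, in which 98.3%, 98.4% and 98.6% of the broad, GABA and Sst genes were found by symbol. Positions are 1-based.

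The alternatives tried were no threshold on adjusted p, a stricter one of 0.001, a minimum log2 fold change of 1, a detection difference of at least 25 points, genes listed in 1 cluster, rankings by detection difference and by detection ratio with 0.01 added, unmatched random lists, 3 other solutions for the shares, parent genes with at least 25% detection, and exon length in place of span. A minimum log2 fold change of 2 was added after the data were seen, as was the pool of matched GABA subclusters as the parent of the Sst set. Comparison between libraries was not analysed here, and some listed genes are not reported here.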

Results

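Nuclei were taken from the lateral septum, a GABAergic forebrain region that receives hippocampal input and projects to the hypothalamus, of 8 untreated male C57BL/6J mice aged 3 months. The tissue was pooled, nuclei were sorted by fluorescence, and 3 droplet libraries of nuclear RNA were made from the pool. The study's title concerns a circuit from dorsal hippocampus through prodynorphin (Pdyn) neurons of the dorsolateral septum to the lateral hypothalamus, and the regulation of feeding by context. All libraries belong to 1 group, so the comparisons are those between clusters of nuclei. The values are those of 3 tables of cluster markers. They cover all nuclei (25 broad clusters), the GABA neurons (22 subclusters) and a set of nuclei labelled Sst (8 subclusters). Clusters carry numbers and no names. For each cluster a table lists 50 genes with the log2 fold change against all other nuclei of that table and the percentage of nuclei in which the gene was detected inside and outside the cluster. The number of nuclei and the depth per nucleus are unknown, and no values per library were used, so no value has a replicate error. A gene absent from a list of 50 may still differ in that cluster. A cluster is said to be led by the genes of largest log2 fold change among those detected in at least 25% of its nuclei; genes detected in fewer nuclei can rank higher.

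Across the broad clusters, 8 carried markers of glia, cortical excitatory neurons, striatal medium spiny neurons or interneurons, and the others stay unnamed. The astrocyte-like cluster 8 listed 7 of the 10 astrocyte markers fixed beforehand, among them the glutamate transporter gene Slc1a3, which in the authors' deposited table had a log2 fold change of 4.34 and was detected in 87.5% of its nuclei against 10.3% of the others. The oligodendrocyte-like cluster 9 listed all 8 oligodendrocyte markers, with the myelin genes Mog (4.44, 38.4% against 2.5%) and Mobp (4.43, 45.0% against 3.4%) in the authors' deposited table. The oligodendrocyte precursor-like cluster 20 listed 6 of 7 precursor markers, of which the highest by log2 fold change was Pdgfra, the receptor of platelet-derived growth factor (5.76, 44.1% against 1.2% in the authors' deposited table). The same cluster also listed 4 of the 5 markers of newly formed oligodendrocytes, with Gpr17, which led the cluster, at 6.15 (27.0% against 0.5%) and Bcas1 at 5.52 (43.0% against 2.1%) in the authors' deposited table.

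Neurons outside the GABA group formed several clusters. Slc17a7, the vesicular glutamate transporter typical of cortex and hippocampus, was listed for clusters 7, 13, 17 and 23, with log2 fold changes of 3.57, 3.06, 2.98 and 2.78 and detection inside of 51.8%, 47.9%, 45.0% and 43.8% in the authors' deposited table. Clusters 13, 17 and 23 each listed 3 of the cortical excitatory neuron markers and are called cortical excitatory neuron-like, while cluster 7 listed fewer and stays unnamed. In the authors' deposited table, cluster 17 had Neurod2 (4.16) and the growth factor gene Bdnf (3.54, 18.7% against 1.6%), and cluster 23 had Tshz2 (6.17, 100% against 7.0%), the neurexin ligand gene Nxph3 (5.45, 34.0% against 0.9%) and Fezf2 (4.79, 19.1% against 0.8%). Slc17a6, the other main vesicular glutamate transporter, was listed for clusters 18 (4.64, 29.8% against 1.3%) and 21 (5.15, 37.9% against 1.3%) in the authors' deposited table. Cluster 18 was led by the transcription factors Ebf3 (7.39, 47.0% against 0.3%) and Ebf2 (7.27, 69.6% against 1.1%) and also had the calcium-binding protein gene Calb2 (5.18, 48.8% against 2.2%), and cluster 21 by Bnc2 (6.79, 50% against 1.1%), with the µ-opioid receptor gene Oprm1 at 3.18 (49.3% against 8.0%) in the authors' deposited table.

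Among the broad clusters matched by the GABA table, the striatal medium spiny neuron-like cluster 14 listed 6 of 11 markers. These included the adenosine receptor gene Adora2a (6.29, 15.2% against 0.3%), the sodium channel subunit gene Scn4b (5.20, 24.2% against 1.0%) and Ppp1r1b, which encodes the dopamine signalling protein DARPP-32 (4.60, 35.6% against 2.5%), in the authors' deposited table. The interneuron-like cluster 16 listed 6 of 13 markers, with Npy at 6.63, Vip at 6.34 and Maf at 5.58 in the authors' deposited table. It also listed 5 neuropeptide genes, more than 99.88% of 10000 random lists matched on detection, and 7 synaptic adhesion genes, more than 99.97%. The neuropeptide genes Npy and Vip and the adhesion gene Nxph1 are also interneuron markers, so these counts partly repeat the name. With a minimum log2 fold change of 2, the neuropeptide and adhesion counts of cluster 16 stayed above 99%, at 99.64% and 99.22%. The adhesion counts of clusters 1 and 3 (99.2% and 99.82% without the minimum) and the cortical excitatory count of cluster 23 (99.69%) did not. Axon guidance genes in cluster 18 passed 99% only with the minimum (99.54%). Potassium channel genes in cluster 21 passed with the minimum (99.32%) and with random lists not matched on detection (99.25%). The adhesion count of cluster 1 did not pass with unmatched lists. Other clusters were led by the basement membrane collagen gene Col15a1 (cluster 0, 3.39, 28.0% against 3.2%), the guidance cue gene Slit2 (cluster 1, 2.06, 51.9% against 17.4%), Cpa6 (cluster 2, 3.06, 78% against 16.8%), Fam19a1 (cluster 5, 3.70, 97.0% against 34.2%), Gpc3 (cluster 11, 3.19, 69.3% against 14.4%) and the secreted phosphoprotein gene Spp1 (cluster 24, 7.68, 52.2% against 0.5%) in the authors' deposited table. Of the lists for microglia, endothelial, mural and ependymal cells, 0 markers were listed for any of the 25 clusters, and 0 mitochondrial and 0 ribosomal protein genes were listed.

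The share of nuclei in each cluster was recovered from the detection percentages, since the weighted mean of detection inside and outside is the same overall detection for every cluster that lists a gene. The broad shares summed to 100.03% ± 0.54 (SD of 1000 resamplings of the genes). By the same resampling, the GABA shares summed to 100.76% ± 0.47, an excess beyond 1 SD, and the Sst shares to 100.1% ± 0.66. Glia-like clusters 8, 9 and 20 held 9.55% ± 0.09 of nuclei, and the 4 clusters listing Slc17a7 held 9.97% ± 0.08 by the same resampling. The pair listing Slc17a6 held 3.20% ± 0.04. The medium spiny neuron-like cluster 14 held 2.06% and the interneuron-like cluster 16 held 2.00%. The largest broad cluster, cluster 0, held 14.95% ± 0.03. These errors cover the rounding and choice of genes, not differences between mice or libraries.

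**Figure D1:**
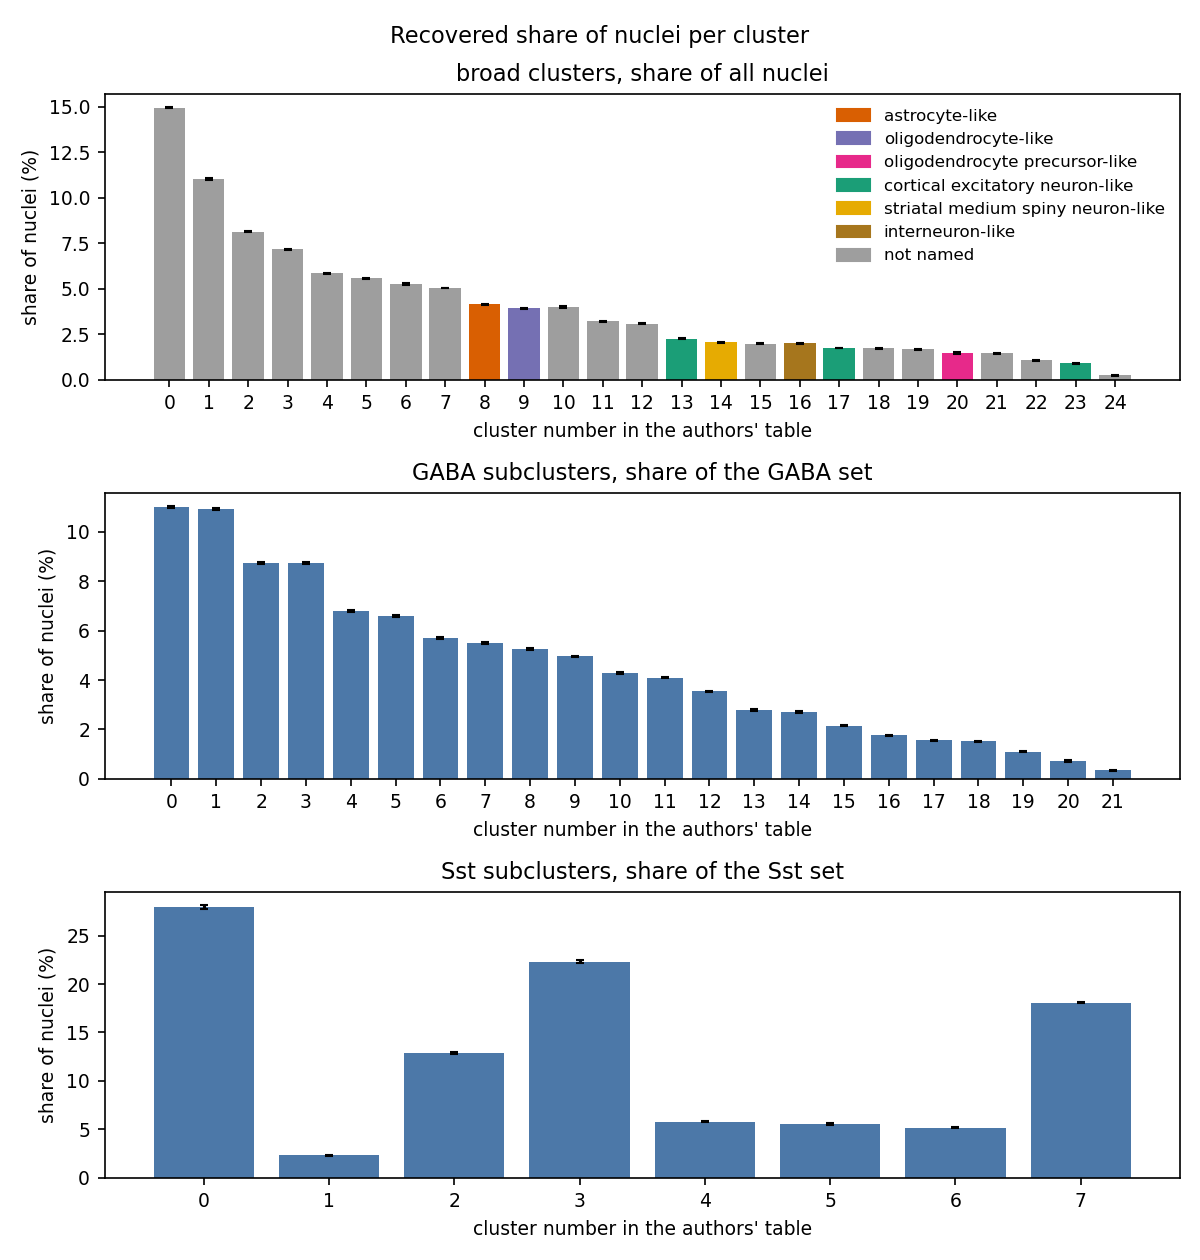
Recovered share of nuclei (%) in each cluster of the 3 tables, by cluster number, with bars of broad clusters coloured by their markers and error lines giving the SD of 1000 resamplings of genes. Shares run from 14.95% for cluster 0 to 0.24% for cluster 24 in the broad table and nearly follow cluster number there and in the GABA table, but not in the Sst table.

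The GABA table compared subclusters of the GABA neurons, which can include neurons of tissue next to the septum. Subcluster 0, the largest at 11% of GABA nuclei, was led, among genes detected in at least 25% of its nuclei, by the carboxypeptidase gene Cpa6 (2.84, 76.9% against 18.0%) and the prolactin receptor gene Prlr (2.25, 40.3% against 10.2%) in the authors' deposited table. Subcluster 1 was led by Hmcn1 (3.62, 31.6% against 3.5%) and Col15a1 (2.74, 30.6% against 5.3%) in the authors' deposited table. Subcluster 5 had the largest log2 fold change for the transcription factor gene Lhx2 at 3.85 (13.1% against 1.0%), followed by Fam19a1 (3.84, 95.9% against 29.7%) and Dach2 (3.77, 56.4% against 10.6%), and had the urocortin receptor gene Crhr2 at 3.26 (20.2% against 2.3%) in the authors' deposited table. With the recovered shares, subcluster 5 held 38.3% of the GABA nuclei in which Crhr2 was detected, from 6.59% of GABA nuclei.

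Of 36 neuropeptide receptor genes, 10 were listed, over 9 of the 22 GABA subclusters, and of 14 feeding-related receptor genes, 4 were listed, over 4. In no subcluster did either group exceed 79.01% of random lists. In the authors' deposited table, the tachykinin receptor gene Tacr1 was listed for subcluster 11 (3.66, 20.7% against 2.0%), the orexin receptor gene Hcrtr2 for 19 (4.15, 20.1% against 1.6%), the δ-opioid receptor gene Oprd1 for 17 (4.54, 16.1% against 0.7%) and the κ-opioid receptor gene Oprk1, whose ligand is made from Pdyn, for 7 (2.10, 4.6% against 1.1%). The incretin receptor gene Glp1r was listed for subcluster 8 (2.51, 3.2% against 0.6%), the dopamine receptor gene Drd3 for 4 (2.86, 8.9% against 1.4%), the oestrogen receptor gene Esr1 for 12 (2.12, 16.5% against 5.6%) and the serotonin receptor gene Htr1a for 10 (2.11, 6.4% against 1.5%) in the authors' deposited table. Calcr and Npy2r were listed for subclusters 12 and 6 from detection of 1.5% and 1.1% inside in the authors' deposited table, against 0.1% outside for each.

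The interneuron-like subcluster 17 (1.57% of GABA nuclei) had Npy (6.43, 26.5% against 1.1%), Moxd1 (5.84, 25.6% against 0.6%), Cort (5.84, 18.2% against 0.4%) and the potassium channel subunit gene Kcnmb2 (5.29, 75.0% against 4.0%) in the authors' deposited table. The interneuron-like subcluster 19 (1.10%) had Vip (7.78, 23.1% against 0.3%), Cck (5.76, 28.6% against 1.7%) and Adarb2 (6.02, 94.9% against 20.7%) in the authors' deposited table. Its 5 listed neuropeptide genes were more than 99.37% of random lists held, against 93.71% for the 3 of subcluster 17 and 97.9% for the 3 of subcluster 20. Of those 5, Vip, Cck and Npy are also interneuron markers, so the count partly repeats the name. Subcluster 20 (0.73%) listed 3 of 11 lateral septum GABAergic neuron markers, Nts, Sst and Meis2, more than 99.47% of random lists. It also listed the interneuron marker Chodl, and its Nts and Sst are among the neuropeptide genes counted above. It was led by the neurotensin gene Nts (4.21, 34.2% against 2.2%) and Fam19a1 (4.06, 100% against 33.6%), with Cartpt at 3.20 (16.8% against 2.1%) in the authors' deposited table. Nts was also listed for subcluster 3 (2.39, 8.9% against 1.8%), which by its larger size held 32.1% of the GABA nuclei with detected Nts, against 10.2% for subcluster 20. Synaptic adhesion genes were listed more often than in 99% of random lists for subclusters 6 (5 genes), 9 (5) and 17 (6), and cadherin genes for subcluster 12 (4), with percentiles of 99.54, 99.29, 99.91 and 99.31. With a minimum log2 fold change of 2, none of these synaptic adhesion, cadherin, neuropeptide or lateral septum counts in the GABA table stayed at the 99th percentile. Nor did the interneuron count of subcluster 17 (99.98% without the minimum), while that of subcluster 19 stayed, at 99.68%. With random lists not matched on detection, the synaptic adhesion calls were for subclusters 4 and 17 in place of 6, 9 and 17.

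**Figure D2:**
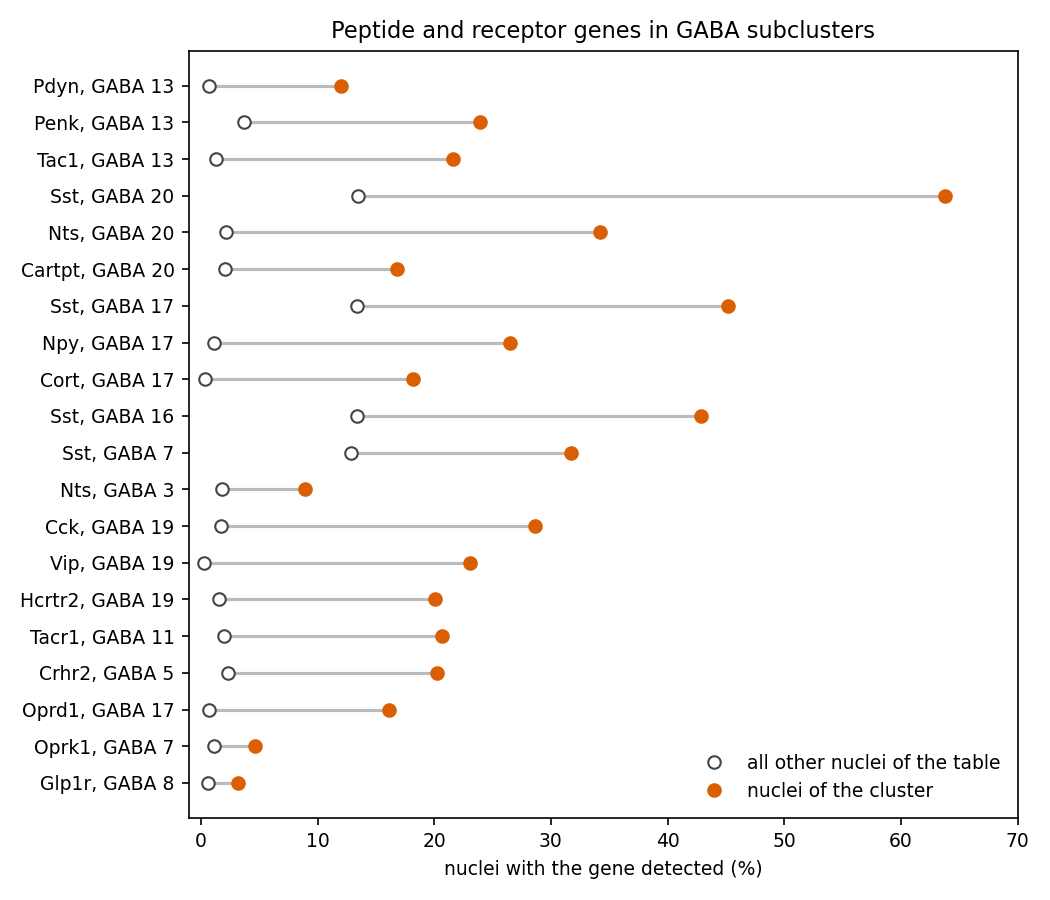
Percentage of nuclei with each peptide or receptor gene detected inside the named GABA subcluster (filled) and in all other GABA nuclei (open), as the authors' deposited table gives them. Sst has the highest detection outside its subclusters of the genes drawn, near 13%, and Pdyn is detected in 12% of subcluster 13 against 0.7% of the others.

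Pdyn, the prodynorphin gene of the study's title, was listed for 1 GABA subcluster and 1 broad cluster, both with striatal medium spiny neuron markers. The 2 shared 43 of their 50 listed genes, so they are not separate results. Striatal tissue can be present, per the labels' protocols, and whether these nuclei are septal was not tested. In the authors' deposited table it had a log2 fold change of 4.43 in GABA subcluster 13, with detection in 12% of its nuclei against 0.7% of other GABA nuclei, and of 4.53 in broad cluster 14, with 12% against 0.6%. Subcluster 13 also had Adora2a (6.46), Scn4b (5.12), Tac1 (4.58), Drd1 (4.39) and the enkephalin gene Penk (3.58) in the authors' deposited table. With the recovered shares, Pdyn was detected in 1.01% of GABA nuclei, and subcluster 13, with 2.78% of GABA nuclei, held 32.9% of those in which it was detected (31.3% to 34.6% from rounding of the percentages). The rest lay in subclusters whose lists do not name Pdyn, and the share of this due to free RNA is unknown. By log2 fold change Pdyn ranked 9 of 50 in GABA subcluster 13, but 47 by the difference in detection, because of its low detection inside. The gene lies on chromosome 2 from 129686565 to 129699844 on the minus strand (GRCm38, GENCODE M21).

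Sst, the somatostatin gene on chromosome 16 from 23889573 to 23890958 on the minus strand (GRCm38, GENCODE M21), had the highest detection outside a listing subcluster of the neuropeptide genes in the GABA table, and the share of this due to free RNA is unknown. It was listed for GABA subclusters 17 (4.00, 45.2% against 13.4%), 20 (2.52, 63.8% against 13.5%), 16 (1.75, 42.9% against 13.4%) and 7 (1.46, 31.7% against 12.9%), and for broad cluster 12 (2.14, 41.6% against 11.2%), in the authors' deposited table. Within the Sst table it was listed for subcluster 1 (1.34, 62.9% against 23.9%) in the authors' deposited table. From the recovered shares, Sst was detected in 13.9% of GABA nuclei and in 24.8% of the nuclei of the Sst table. Pdyn was listed for 0 of the 8 Sst subclusters.

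The Sst table compared 8 subclusters of its nuclei with one another. Sst was detected in 24.8% of these nuclei, so Sst nuclei here means nuclei of that table, not neurons shown to express Sst. Of its 353 listed genes, 311 were listed for 1 subcluster. Subcluster 0 (27.95% ± 0.19 of the Sst nuclei, SD of 1000 resamplings) had Stk31 (2.48, 32% against 8.5%), the synaptic adhesion genes Il1rapl2 (2.32, 79.1% against 43.8%) and Cntn5 (1.93, 85.3% against 43.0%), and Nts (1.71, 8.9% against 2.8%) and Penk (1.68, 9.7% against 4.0%) in the authors' deposited table. Subcluster 1, at 2.32%, listed the same 3 lateral septum markers, Nts, Sst and Meis2, more than 99.66% of random lists. Its best match was GABA subcluster 20, so this is not a separate result. It also listed the interneuron marker Chodl and the oligodendrocyte precursor marker Vcan. It had Fam19a1 (5.77, 100% against 26.3%), Nts (3.36, 33.8% against 3.8%), Cartpt (3.56, 16.6% against 1.8%) and Zbtb20 (3.11, 92.7% against 35.2%) in the authors' deposited table. Subcluster 3, at 22.32%, had Car10 (2.06, 73.9% against 31.2%), the heparan sulphate enzyme gene Hs6st3 (1.85), the calcium release channel gene Itpr1 (1.68, 41.4% against 15.5%), the glutamate receptor subunit gene Grin3a (1.64) and Drd3 (2.12, 8.6% against 2.1%) in the authors' deposited table, and its 5 synaptic adhesion genes exceeded 99.26% of random lists, as the 5 of subcluster 6 exceeded 99.22%. Neither synaptic adhesion count stayed at the 99th percentile with a minimum log2 fold change of 2 or with unmatched random lists, and the lateral septum count of subcluster 1 did not with the minimum.

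Subcluster 2 had the transcription factor gene Etv1 (2.44, 37.6% against 7.4%), Plpp4 (2.40) and the cannabinoid receptor gene Cnr1 (2.11, 34.9% against 9.8%) in the authors' deposited table. Subcluster 5 had its largest log2 fold change for Oprk1 at 4.21 (14.1% against 0.8%), and among genes detected in at least 25% of its nuclei for the glypican gene Gpc5 (3.50, 95.9% against 39.7%), Stxbp6 (3.15, 62.2% against 12.2%) and Lmo4 (3.00, 62.7% against 14.2%) in the authors' deposited table. It held 51.0% of the Sst nuclei with detected Oprk1, from 5.57% of the Sst nuclei. Subcluster 4 had Cpa6 (4.33, 85.5% against 12.3%), Pappa (2.86), Rarb (2.50), and the serotonin receptor genes Htr7 (2.03, 38.4% against 10.7%) and Htr2c (1.90, 86.3% against 35.8%) in the authors' deposited table. The interneuron-like subcluster 6 listed 6 interneuron markers, with Npy (7.70, 26.5% against 0.8%), Maf (6.33, 37.8% against 0.8%), Sox6 (5.07, 67.6% against 5.7%) and Lhx6 (5.70, 9.5% against 0.2%), beside Moxd1 (6.99, 25.6% against 0.3%), in the authors' deposited table. Subcluster 7, at 18.09%, had Col15a1 (3.13, 32.5% against 4.3%), Nfib (2.54, 75.3% against 22.1%), Prlr (1.93, 16.4% against 4.6%) and the serotonin receptor gene Htr1b (1.99, 11.2% against 2.9%) in the authors' deposited table; Prlr was named after its values were seen.

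**Figure D3:**
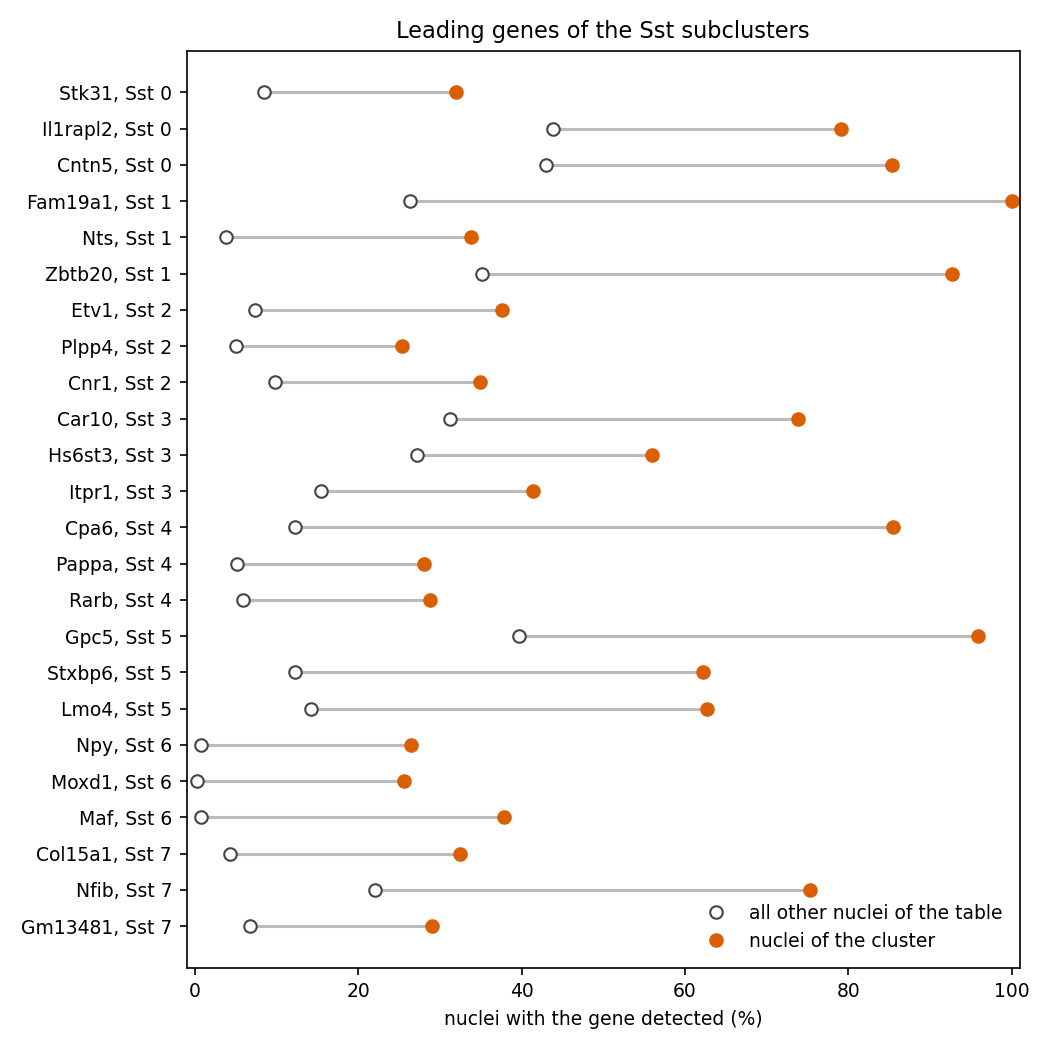
Percentage of nuclei with each gene detected inside an Sst subcluster (filled) and in the other Sst nuclei (open), for the 3 genes of largest log2 fold change per subcluster with at least 25% detection inside, as the authors' deposited table gives them. Detection inside runs from 25.4% for Plpp4 to 100% for Fam19a1.

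The 3 tables were then compared with each other. By shared genes and detection inside, Sst subclusters 0, 1, 3, 4, 6 and 7 had as best matches GABA subclusters 3, 20, 4, 16, 17 and 8, and Sst subclusters 2 and 5 both had GABA subcluster 7. For the first 6 the median gap in detection of the shared genes was at most 0.6 percentage points, against 2.6 and 9.4 points for Sst subclusters 2 and 5. The 7 matched GABA subclusters made up 30.3% ± 0.2 of GABA nuclei. Their relative sizes differed from those of the Sst subclusters by at most 0.9 points, a gap as small in 1 of 10000 random sets of 7 GABA subclusters. The random sets were not picked as best matches, so this count only describes how close the sizes were. The gaps were 4.1 times the resampling SD for GABA subcluster 3 and 6.5 times for 8, and at most 1.6 times for the other 5. Sst itself, in the authors' deposited table, was among the 50 genes of GABA subclusters 7, 16, 17 and 20 and not of 3, 4 and 8.

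The GABA subclusters matched 15 broad clusters holding 75.3% ± 0.4 of all nuclei, and the other 10 broad clusters, which include the glia-like and Slc17a7-listing ones, held 24.7% ± 0.2 (SD of 1000 resamplings of genes). GABA subclusters 17 and 19, which both list Npy, matched the interneuron-like broad cluster 16. The medium spiny neuron-like GABA subcluster 13 matched broad cluster 14 with 43 shared genes and a median gap of 0.2 points.

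**Figure D4:**
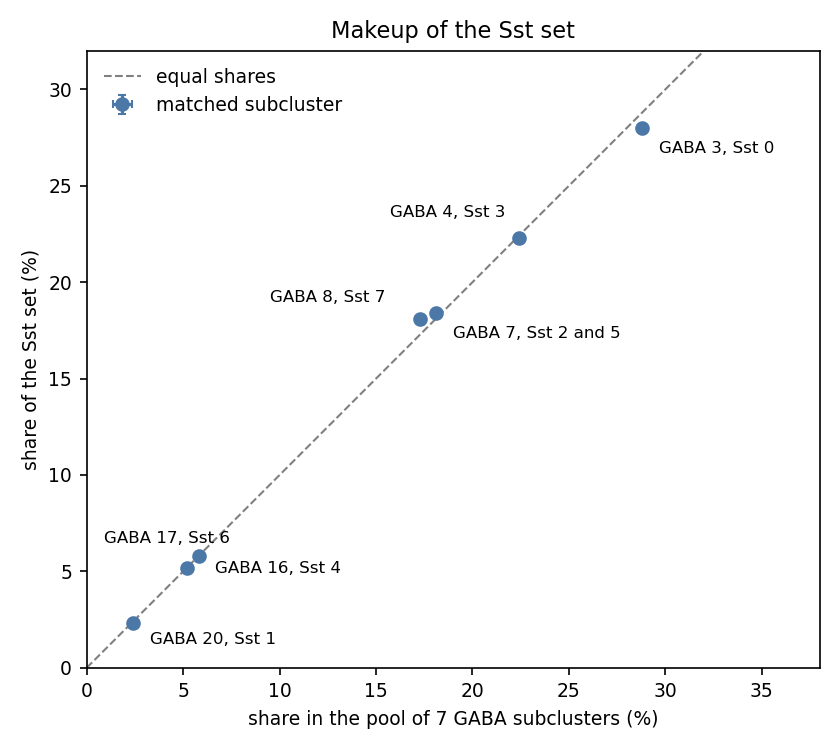
Share of each matched GABA subcluster in the pool of 7 (horizontal axis, %) against the share of its matching Sst subclusters in the Sst set (vertical axis, %), with error lines of 1 SD over 1000 resamplings of genes and a dashed line of equal shares. The points lie within 0.9 percentage points of the line.

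Clusters within a table shared few genes. The median pair of broad clusters had 1 gene in common, of GABA subclusters 2 and of Sst subclusters 1. The largest overlap was between the cortical excitatory neuron-like broad clusters 13 and 23, with 20 genes. Among GABA subclusters it was 15 genes, between 5 and 11, and the interneuron-like 17 and 19 shared 14. Sst subclusters 2 and 5 shared 9.

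Marker genes were long. The median gene span was 133.0 kb for broad markers, 154.4 kb for GABA markers and 178.2 kb for Sst markers, against 17.4 kb for the 21951 protein-coding genes of the annotation. Among the broad clusters the median ran from 52.5 kb in the oligodendrocyte-like cluster 9 to 390.1 kb in the Slc17a7-listing cluster 7. Across genes, which are not independent replicates, span and detection outside the cluster had a Spearman rho of 0.70 in the broad and GABA tables and 0.72 in the Sst table. The peptide genes fell at the short end, with Sst spanning 1.4 kb, Npy 6.8 kb, Nts 8.7 kb and Pdyn 13.3 kb.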

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

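The threshold of 2 on log2 fold change was chosen after seeing the data. Of the alternatives, 34 stayed within tolerance and 28 moved beyond it. Tolerance is 1.5 times for a count, detection gap or length, 1 resampling SD for a share and no change for a rank. A value within tolerance can still differ. The 34 include settings that could remove no listed gene, so the tally overstates stability. Dropping the threshold on adjusted p, tightening it to 0.001, or asking for a log2 fold change of 1 removed 0 listed genes, so these settings test nothing. A detection difference of 25 points left 693 broad, 460 GABA and 156 Sst markers of 1250, 1100 and 400. A log2 fold change of 2 left 669, 424 and 159. Genes listed in 1 cluster numbered 548 in the broad table and 447 in the GABA table. Under the threshold of 2, pairs of a gene list and a cluster at the 99th percentile fell from 9 to 2 in the GABA table and from 4 to 1 in the Sst table, leaving the striatal list in GABA subcluster 13 and the interneuron list in GABA subcluster 19 and Sst subcluster 6, and the most genes shared by Sst subclusters fell from 9 to 2, since fewer genes were counted. In the broad table the threshold of 2 gave 12 such pairs in place of 13, not all of them the same. Unmatched random lists gave 2 such pairs in the Sst table. By detection difference, Pdyn ranked 45 in broad cluster 14 and 47 in GABA subcluster 13 in place of 6 and 9, and by ratio 7 and 19. Sst in Sst subcluster 1 moved from 43 to 12 and 33, and the cause was not tested. Ranking by detection difference kept 16 of 50 leading genes in the broad table, 14 of 44 in the GABA table and 13 of 40 in the Sst table.

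Forcing shares to sum to 1 gave 10.95% for GABA subcluster 0 and 30.07% for the matched GABA subclusters, by construction. Of all 55 shares, that setting moved 8 by more than their resampling SD, least absolute deviations moved 4 and genes with a detection difference of at least 0.1 moved 0, and the largest move of any share was 0.10 points. The smallest gap in median detection between the Sst set and a single GABA subcluster rose from 6.8 to 15.7 points, and between the GABA set and a single broad cluster from 6.1 to 16.3, with genes of at least 25% detection in the parent. Exon length in place of span gave medians of 6.28, 6.40 and 6.81 kb for the broad, GABA and Sst tables. No paired analysis was possible because the results come from tables over pooled libraries, and for the same reason leaving out each library was not run. Unknown depth limits what low detection, such as that of Glp1r and Pdyn, can show.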

Other observations

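The tests of explanations below were all chosen after the pattern was seen. Transcription factor and calcium-binding genes were listed for several GABA subclusters, at no more than 82.64% and 88.75% of random lists in any of them. The transcription factor gene Pax6 was listed for subcluster 18 (5.29, 23.0% against 0.6%), Nkx2-1, a factor of ventral forebrain development, for 6 (4.08, 9.9% against 0.6%) and Foxp2 for 9, 15 and 21 (2.28, 2.93 and 2.98) in the authors' deposited table. The calcium-binding protein gene Necab1 was listed for subclusters 21, 18, 15, 20 and 7 (3.30, 2.83, 2.19, 1.77 and 1.39), and Calb1 for 17, 11 and 5 (3.10, 2.59 and 1.74) in the authors' deposited table. The smallest subcluster, 21, with 0.35% of GABA nuclei, was led by Spp1 (7.54, 51.4% against 0.5%) and the transcription factor gene Six3 (4.83, 38.6% against 2.3%) in the authors' deposited table, and shared 49 of its 50 genes with broad cluster 24. Of 13 immediate early genes, 1 was listed in each table: Bdnf in broad cluster 17, and Junb in GABA subcluster 3 (1.45, 11.4% against 4.9%) and in Sst subcluster 0 (1.08, 11.4% against 6.0%) in the authors' deposited table.

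The nuclei of the Sst table had Sst detected in 24.8% of cases, so gating of nuclei on a detected Sst transcript is argued against. Pooling of 7 whole GABA subclusters with no nuclei moved between them is argued against too, since the largest size gap, 0.9 percentage points, lay beyond its resampling error. Pooling followed by a new clustering that moved some nuclei may account for the close sizes and stays open, as untested. If the set were that pool, 54.1% of the GABA nuclei with detected Sst lay in it. Pdyn would then be detected in at most 2.2% of its nuclei. That bound lies above the 1.01% of all GABA nuclei with detected Pdyn, so it does not show Pdyn to be scarce there. No biological explanation was tested, since the design has 1 group.

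Ttr, which encodes transthyretin and is abundant in choroid plexus, was listed for GABA subcluster 0 (2.35, 5.5% against 1.1%) and broad cluster 2 (2.50, 5.3% against 1.0%) in the authors' deposited table. Free choroid plexus RNA spread evenly over nuclei would give a like share everywhere. Detection was 5.0 times as high inside subcluster 0 as outside (4.74 to 5.29 from rounding). A gap in this direction was needed for the listing itself, and depth per nucleus is unknown, so the ratio does not decide the question. Nuclei joined with choroid plexus cells could bring other choroid genes, and 0 of Folr1, Kl and Clic6 were listed for subcluster 0. This absence excludes nothing, because the list ends at 50 genes, and Clic6 was listed for broad cluster 4 (1.64, 22.5% against 8.2%) in the authors' deposited table. Expression of Ttr by these neurons was not tested.

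Marker genes are long at the median, and capture of intronic reads of long genes in nuclei may contribute. Given exon length, the rank correlation of span with detection outside the cluster was at least 0.60 in the 3 tables, while that of exon length given span was 0.06 in each, values that the explanation needs. Genes are not independent, and the length of genes used by neurons, a biological alternative, was not tested. The short peptide genes Pdyn and Sst may be under-detected relative to long genes on this account, which was not measured.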
